A study of Homo sapiens with 12 samples.

How the data were processed

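Lamina-associated domains (LADs), the stretches of DNA that touch the nuclear lamina, were mapped in the H9 human embryonic stem cell line by pA-DamID. In this assay an antibody against lamin B1 (LMNB1), a protein of the lamina, tethers a fusion of protein A and the bacterial Dam methylase. The enzyme marks adenines in nearby GATC sites, and the marked fragments are amplified and sequenced. Libraries made with untethered Dam (Dam-only) serve as the control for accessibility. The labels describe 12 libraries in 4 groups of 3, namely LMNB1 and Dam-only libraries of cells kept in mTeSR (primed) and of cells kept in RSeT (naive). They do not say whether the 3 libraries of a group came from separate cultures.

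The deposited files hold 1 list of LAD intervals per state. Each list gives chromosome, start and end, with no score, read number or signal. Per the labels, the lists are called final, while the files used here are named as simple lists. What sets these apart is not given in the sources used here, so LAD numbers, lengths and gaps hold for the lists used. The submitters' processing notes name BWA, SAMtools 1.10, SICER and the build hg38. The order of the steps, the thresholds and the way the 3 LMNB1 and 3 Dam-only libraries of a state were combined are not given in the sources used here. In both lists all starts and ends were multiples of 10 kb, and no 2 intervals of a list touched, so the LADs are runs of 10 kb windows. The sequencing depth behind a window is unknown, and windows with few mappable reads or few GATC sites cannot be told from windows away from the lamina. Because the lists do not keep replicates apart, no difference between the states could be set against replicate error, and no p-value is given for one.

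All values were computed from the deposited interval coordinates. The 22 autosomes and X were analysed, each from its first base to the end of its last annotated gene or LAD, which gave a span of 3030 Mb (3029.94 Mb before rounding). Gene positions came from the RefSeq table of GRCh38.p14, the same primary assembly as hg38, with 19974 protein-coding genes among 59098 genes. A gene was placed in a LAD when at least 50% of its body was covered. Coordinates are 1-based. The spread of base shares along the genome was estimated by resampling 619 blocks of at most 5 Mb 1000 times (95% intervals). These intervals cover placement along the genome and not replicate error. Exact binomial (Clopper-Pearson) intervals of shares of genes, LADs or windows take each of these as independent. Neighbouring genes often share a LAD, so the exact intervals are likely too narrow for placement along the genome, and they do not cover replicate error either. The agreement of both lists was set beside 1000 shifts of the naive LADs round each chromosome. Correlations over chromosomes used 100000 permutations, two-sided.

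Before the data were examined, 15 gene lists (373 genes, all matched, 2 of them by an older symbol) and 18 gene families defined by symbol were fixed. Each list's count in LADs was placed among 10000 random lists of protein-coding genes of the same size and the same mix of 10 gene length groups, as a percentile that describes these lists and tests no difference between states. Placement shifted round the chromosomes was the alternative. The rule for named genes was fixed at the same time. In each list, up to 4 members per direction that lay in LADs of 1 state only are named, by the largest difference in covered share and then by length. Where no member differed, up to 3 members in LADs of both states are named, the longest first. Of all protein-coding genes, the 10 per direction with the largest difference are named, and the 5 longest stretches per direction are given with up to 4 genes lying wholly inside. Chromosomes 13, 14, 15, 18, 19, 21, 22 and X were to be named, and DUX4, ZSCAN4, LMNB1, POU5F1, SOX2 and NANOG are given whatever their values. Some genes that this rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

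Alternatives joined LADs less than 50 or 100 kb apart, left out LADs under 50 or 100 kb, did both, used autosomes only, changed the overlap that counts as shared or the share of a gene that must be covered, and used all genes. The share of bases in LADs of 1 Mb or longer, gene counts with a difference of at least 50 points and the counting of loci instead of genes were added after seeing the data. The functions were tested on simulated data: of 19974 genes, 200 were switched between 2 simulated lists made from the primed LADs, 200 were recovered and 0 genes were called outside the switched windows. For an independently placed list, the overlap was 0.947 times the mean of 200 shifts. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.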

Results

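The data comprised 2 LAD lists from H9 human embryonic stem cells, 1 for the naive state (RSeT medium) and 1 for the primed state (mTeSR medium). Each stood for 3 LMNB1 and 3 Dam-only libraries. The series set these states side by side to ask which loci lie at the lamina in each of them. With 1 list per state there are no replicates, so differences between the states are given as values of these lists and were not tested.

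Naive LADs covered slightly more of the genome than primed LADs and were cut into more pieces, with less of their DNA in LADs of 1 Mb or longer. The naive list held 9178 LADs covering 1438 Mb, or 47.5% of the 3030 Mb span (interval over 5 Mb blocks 44.5% to 50.5%). The primed list held 5671 LADs covering 1319 Mb, or 43.5% (40.5% to 46.7%). The difference within blocks was 3.93 percentage points (3.09 to 4.87), and over the alternatives it ran from 1.68 to 5.86 points. The median length was 20 kb in both lists (quartiles 10 and 90 kb in naive, 10 and 60 kb in primed), and the mean was 157 kb in naive and 233 kb in primed. The medians were low because single 10 kb windows made up 40.1% of the naive and 45.8% of the primed LADs. These windows held only 2.56% and 1.97% of the LAD bases. LADs of 1 Mb or longer numbered 393 in naive and 362 in primed, and they held 47.6% of the naive but 73.4% of the primed LAD bases. The longest naive LAD was 5.52 Mb, on chromosome 10 (104360001 to 109880000), and the longest primed LAD was 10.23 Mb, on chromosome 13 (68360001 to 78590000). Naive LADs were separated by a single window at 4769 places and primed LADs at 2584. The contrast in long LADs depended on gaps under 50 kb, of which there were 7263 in naive and 4169 in primed: with LADs less than 50 kb apart joined, those of 1 Mb or longer held 88.3% of the naive and 91.7% of the primed LAD bases.

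**Figure D1:**
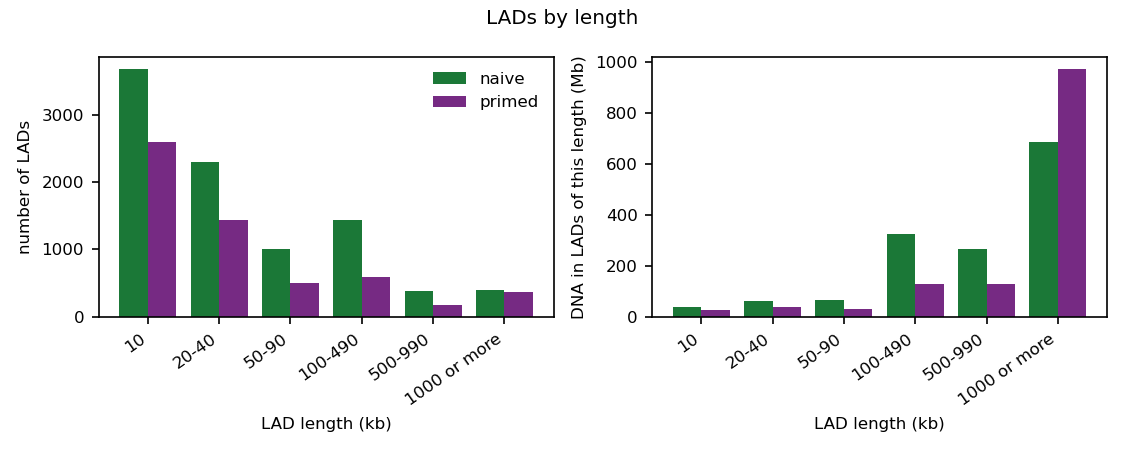
Number of LADs (left) and DNA they hold in Mb (right) by LAD length in kb, for the naive and primed lists. Naive has more LADs in each length class, while LADs of 1000 kb or more hold 685 Mb in naive and 969 Mb in primed.

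Most lamina-associated DNA was common to both states. The lists shared 1244 Mb, which was 94.3% of the primed LAD bases (93.5% to 94.9%) and 86.5% of the naive LAD bases (84.7% to 88.2%). A further 194 Mb was in naive LADs only and 75.4 Mb in primed LADs only. The Jaccard index, the shared bases over the bases in either list, was 0.822 (0.804 to 0.838). Over 1000 shifts of the naive LADs round the chromosomes it averaged 0.347 ± 0.0187 (SD), with a highest value of 0.434, so the observed overlap was 2.37 times the mean and above all shifts. The shifts also move LADs into assembly gaps and other windows that cannot be called, which lowers the shifted overlap. How much of the excess comes from this was not tested. Sharing depended on length. Of LADs of 1 Mb or longer, 99.0% of the naive and 100% of the primed ones had at least 50% of their length in the other list, against 24.5% of the naive and 53.8% of the primed 10 kb LADs. Primed LADs covered 43.5% and naive LADs 47.5% of all windows. The naive 10 kb LADs thus lay in the other list less often than windows at large, and the primed ones little more often. Shared windows held 2.45 protein-coding gene midpoints per Mb, naive-only windows 3.95, primed-only windows 5.87 and windows in neither list 10.4.

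LAD coverage differed far more between chromosomes than between states. Chromosome 4 was the most covered in both lists, at 72.3% in naive and 73.2% in primed. Chromosomes 19 and 22 were almost free of LADs: 5 naive and 9 primed windows were called on chromosome 19, and 3 in each state on chromosome 22. Of the chromosomes that carry the ribosomal DNA arrays, named because the series title refers to the nucleolus, chromosome 13 was covered at 52.3% in naive and 51.1% in primed. Chromosome 14 was covered at 36.4% and 35.1%, chromosome 15 at 24.0% and 19.04%, and chromosome 21 at 26.2% and 26.8%. The spans start at the first base and include assembly gaps, which cannot hold a LAD and lower these shares. In the first 5 Mb of chromosomes 13, 14, 15, 21 and 22 neither list had a LAD. Whether the ribosomal DNA arrays lie at the lamina thus cannot be read from these shares. Coverage was higher in naive on 18 of 23 chromosomes, with an interval over blocks above 0 on 15 of them. Chromosome 18 had the widest gap, 56.1% in naive against 46.9% in primed (difference 9.12 points, 3.24 to 16.7). Coverage was higher in primed on chromosomes 4, 19, 21 and X, with no interval below 0. On X it was 47.7% in naive and 49.6% in primed, a difference of -1.85 points (-6.14 to 3.28), which became 0.37 points once LADs less than 50 kb apart were joined and -5.46 points without LADs under 100 kb. Chromosomes 4 and 21 moved likewise, to 0.68 and 0.77 points when joined and to -3.58 and -5.61 points when filtered, and with that filter chromosomes 13 and 14 also turned to primed (-1.09 and -2.53 points). Across the 23 chromosomes coverage went down with protein-coding gene density. Pearson's r was -0.687 in naive (permutation p = 8e-05, adjusted over 3 relations 0.00012) and -0.680 in primed (p = 5e-05, adjusted 0.00012). Spearman's rho was -0.718 (p = 0.00026, adjusted 0.00039) and -0.728 (p = 0.00017, adjusted 0.00039). Without chromosomes 19 and 17, the densest of them, r was -0.592 and -0.636. The naive minus primed difference was not related to gene density (r = -0.177, p = 0.45, adjusted 0.45, rho = 0.0455, p = 0.84, adjusted 0.84).

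**Figure D2:**
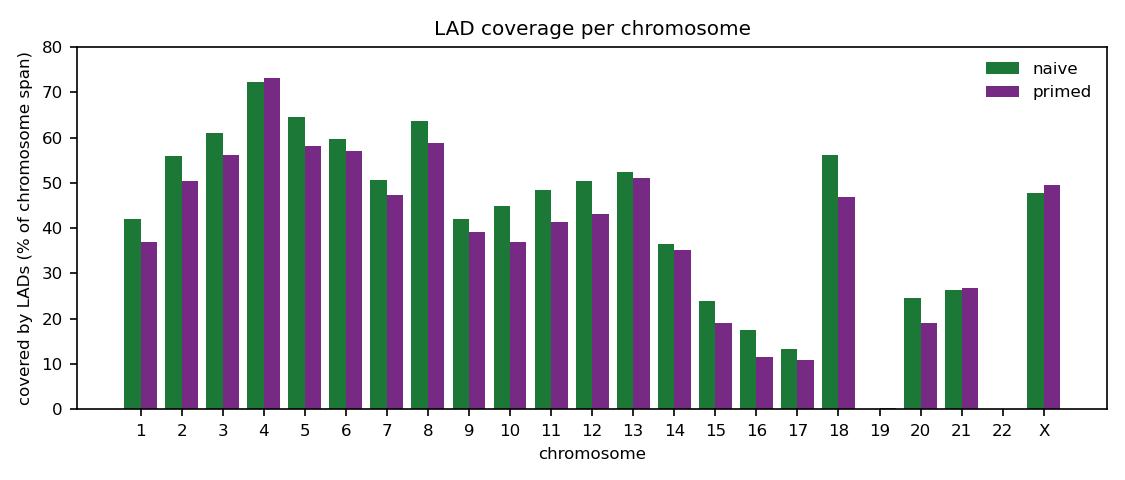
Percent of each chromosome's span covered by LADs in the naive and primed lists, 1 bar per list. Chromosome 4 is covered above 70% in both (72.3% and 73.2%), and the bars of chromosomes 19 and 22 are too low to see.

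In the lists as deposited, the 5 longest naive-only stretches ran from 660 kb to 1.17 Mb and the 5 longest primed-only stretches from 270 to 710 kb. The order of the longest turned without LADs under 50 kb (1170 kb in naive, 1480 kb in primed) and without LADs under 100 kb (1240 and 1710 kb). The longest was 1.17 Mb on X (6030001 to 7200000) and held PUDP, a pseudouridine 5'-phosphatase gene, and VCX3A, with the synaptic adhesion gene NLGN4X reaching into it. It was followed by 750 kb on chromosome 8 (19020001 to 19770000) with CSGALNACT1, a chondroitin sulfate synthesis gene, and SH2D4A. A stretch of 730 kb on chromosome 12 (13270001 to 14000000) held GRIN2B, which encodes an NMDA receptor subunit. The next were 660 kb on chromosome 2 (7900001 to 8560000), without a protein-coding gene, and 660 kb on chromosome 3 (171330001 to 171990000) with PLD1 and TMEM212. In primed only, the longest were 710 kb (93160001 to 93870000) and 490 kb (94060001 to 94550000) on chromosome 13. The first overlapped the glypican gene GPC6 and the second held DCT, a gene of melanin synthesis. They were followed by 340 kb on X (98340001 to 98680000) and 280 kb on chromosome 5 (94630001 to 94910000), neither with a whole protein-coding gene inside. The fifth was 270 kb on chromosome 14 (60720001 to 60990000), with MNAT1, a gene of the CDK-activating kinase, and TRMT5. Stretches of 100 kb or longer numbered 264 in naive only and 30 in primed only. Single windows made up 60.9% of the 7994 naive-only and 78.5% of the 5044 primed-only stretches.

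Of 19974 protein-coding genes, 3766 lay in naive LADs (18.9%, exact binomial interval with genes taken as independent 18.3% to 19.4%) and 3457 in primed LADs (17.3%, 16.8% to 17.8%). Both states shared 3079 of them, 687 were in naive LADs only, 378 in primed LADs only and 15830 in neither. Naive-only genes were longer (median 49.8 kb) than primed-only genes (21.3 kb). Of these, 163 were wholly inside naive and wholly outside primed LADs, and 116 the reverse. With at least 90% of the gene body required in place of 50%, the order of the totals turned, to 2896 genes in naive and 2916 in primed. With LADs less than 50 kb apart joined, 515 of the 687 naive-only and 191 of the 378 primed-only genes kept their call. These shared numbers went down to 328 naive-only genes without LADs under 100 kb and to 131 primed-only genes with LADs less than 100 kb apart joined.

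The 10 longest of the genes fully covered in naive and not at all in primed were GRIN2B, PUDP, CSGALNACT1, TGFBR3, PLD1, CYFIP2, SLC7A14, ST3GAL1, SLC28A3 and NID1. GRIN2B (chromosome 12, 13537337 to 13982134) spans 445 kb, TGFBR3, which encodes betaglycan, 226 kb on chromosome 1, and NID1, a basement membrane nidogen, 89.3 kb on chromosome 1. Among the 10 longest in the reverse direction were MNAT1, the read-through gene CCDC169-SOHLH2, DCT, USP53, CCDC169, PTCHD1, TBC1D23, SOHLH2 and YTHDC1. MNAT1 (chromosome 14, 60734761 to 60969965) spans 235 kb. CCDC169-SOHLH2 spans 130 kb on chromosome 13 and overlaps CCDC169 and SOHLH2, a germ cell transcription factor gene, so these 3 count as 1 locus. YTHDC1, which encodes a reader of N6-methyladenosine, spans 39.7 kb on chromosome 4. All 10 naive-only genes kept their call under each of the 5 settings that joined or filtered the LADs. Of the primed-only genes named here, TBC1D23 alone lost it, under 1 of them.

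Most markers of the 2 pluripotent states lay outside LADs in both lists, 19 of the 25 naive and 16 of the 24 primed ones. Of 25 genes of naive pluripotency, 3 lay in naive LADs and 6 in primed LADs, and the 3 that differed were all in primed LADs only. These were DPPA5 (chromosome 6, 73353063 to 73354276), KHDC3L (73362658 to 73364171) and OOEP (73368555 to 73395163), neighbours in 1 cluster. KHDC3L and OOEP encode parts of the maternal subcortical complex of the oocyte. DPPA5 and KHDC3L were covered at 0% in naive and 100% in primed, and OOEP at 0% and 62.4%. Of 24 genes of primed pluripotency, 7 lay in naive LADs and 4 in primed LADs. DUSP6, an ERK phosphatase gene (chromosome 12, 89347235 to 89352501), was covered at 100% in naive and 0% in primed. NLGN4X (X, 5890042 to 6228867) was covered at 97.0% and 0%, PTPRZ1, a receptor tyrosine phosphatase gene (chromosome 7, 121873161 to 122062036), at 72.5% and 0%, and the stanniocalcin gene STC1 (chromosome 8) at 100% and 37.3%. VCAN, the gene of the proteoglycan versican (chromosome 5), went the other way, at 0% and 83.5%. DPPA5, KHDC3L, NLGN4X and VCAN kept their call under all 5 settings that joined or filtered the LADs, PTPRZ1 under 4 and OOEP under 3, whereas DUSP6 kept it under 2 and STC1 under 1. The naive markers stood at percentile 42.6 of random lists in naive and 93.6 in primed, the primed markers at 88.9 and 45.9. Against shifted placement the percentiles were 0.05 and 5.30 for the naive markers and 0.70 and 0.05 for the primed markers.

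**Figure D3:**
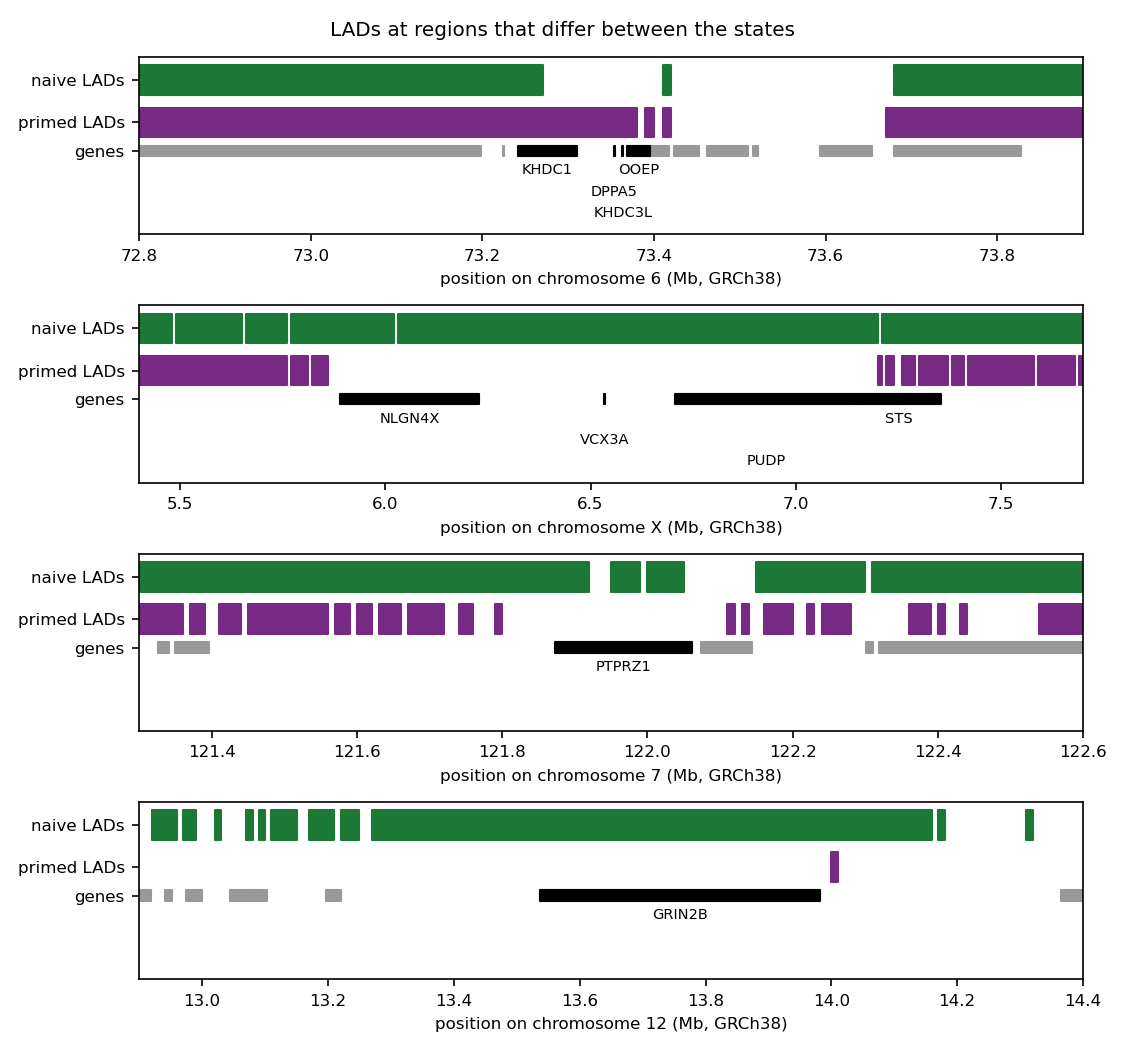
LADs of the naive and primed lists and protein-coding genes (grey, named ones black) along 4 regions, with position in Mb. DPPA5 and KHDC3L lie past the end of a naive LAD and in a long primed LAD, OOEP lies partly in primed LADs (62.4%), while NLGN4X, PUDP, PTPRZ1 and GRIN2B lie in naive LADs and outside primed LADs in all or most of their length.

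None of the 16 core pluripotency genes lay in LADs of either state, among them POU5F1, SOX2 and NANOG, each covered at 0% in both. LMNB1 itself was also covered at 0% in both. The core genes stood at percentile 3.5 of random lists in naive and 4.1 in primed. With LADs less than 50 kb apart joined, 0 core genes lay in naive and 1 in primed LADs. With LADs less than 100 kb apart joined, the counts were 2 and 1. Of 47 genes of the 8-cell embryo, 10 lay in naive LADs (percentile 92.3 of random lists) and 11 in primed LADs (96.8), with 9 in both. Against shifted placement the percentiles were 11.55 and 26.8. KDM4E, of a histone demethylase family, was in naive LADs only (100% and 0%). The homeobox gene DUXB (0% and 100%) and KHDC1 (41.5% and 100%), which lies next to the DPPA5 cluster, were in primed LADs only. DUX4 and ZSCAN4, regulators of the 8-cell programme, were covered at 0% in both states. DUX4 and the TRIM and PRAME families have near-identical copies, and the handling of reads that map to several copies is not given in the sources used here, so their calls are uncertain. None of the 24 PRAME family genes lay in LADs of either state.

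Developmental regulators lay mostly outside LADs in both states. The percentiles among random lists of genes of like length in naive and primed were 44.7 and 24.9 for neuroectoderm, 22.4 and 24.9 for mesendoderm and 43.0 and 28.5 for trophoblast genes. Against shifted placement they were 0 and 0 for both sets of regulators and 0.15 and 0.10 for trophoblast genes. Shifted LADs do not avoid genes as the observed LADs do, so these low values do not set developmental regulators apart. Solute carriers, at 89.0 and 69.2 among random lists, were also at 0 and 0 against shifts. Of 24 neuroectoderm regulators, 3 were in naive and 2 in primed LADs, the difference being PAX3, a neural crest and dorsal neural tube regulator (70.7% and 0%). Of 24 mesendoderm regulators, the same 2, CER1 and MSGN1, were in LADs of both states. With LADs less than 50 kb apart joined, these counts were 6 and 5 for neuroectoderm and 6 in each state for mesendoderm regulators. None of the 39 HOX genes, targets of Polycomb repression, and none of the 51 clustered protocadherins were in LADs of either. Of 30 trophoblast genes, 4 were in naive and 3 in primed LADs, and 8 and 4 with LADs less than 50 kb apart joined. Without LADs under 50 kb the order turned, to 2 and 3. ERVW-1, the syncytin-1 gene (83.1% and 0%), CYP19A1, the aromatase gene (62.8% and 0%), and TFAP2B (65.8% and 5.62%) were in naive LADs only. CGA, the alpha subunit of chorionic gonadotropin (0% and 100%), and ENPEP (49.2% and 88.8%) were in primed LADs only. Of 24 germline genes, 9 were in naive LADs (percentile 99.2) and 7 in primed LADs (94.9), the difference being TDRD1, a piRNA pathway gene (91.1% and 0%), and MAGEA4 (100% and 40.7%). Against shifted placement the germline percentiles were 15.25 and 4.30.

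Few genes of Polycomb complexes, the nucleolus and other widely used functions were in LADs. Among random lists, the percentiles in naive and primed were 3.65 and 5.48 for PRC2 and PRC1 subunits, 18.1 and 22.3 for nucleolar factors and 1.19 and 2.10 for lamina and envelope genes. Of 30 PRC2 and PRC1 subunits, the same 2, PCGF5 and RNF2, were in LADs of both states. The same held for TAF1A and WDR75 of 25 nucleolar factors, and for SYNE1 of 24 lamina and envelope genes. TAF1A was in primed LADs only once LADs under 50 kb were left out, and RNF2 in naive LADs only without LADs under 100 kb. No member of the list of X-inactivation centre and X-linked dosage genes (14 genes from several parts of X) was in LADs of either state. Of 84 ribosomal protein genes, 1 was in naive and 3 in primed LADs, and RPL37 and RPS12 were covered at 0% in naive and 100% in primed. Both lost that difference once LADs less than 50 kb apart were joined. Of 77 mitochondrial ribosomal protein genes, 4 were in LADs of each state, MRPL44 and MRPL3 in naive only (100% and 92.7%, against 0%) and MRPS30 and MRPL50 in primed only (100% against 0%). MRPL44, MRPS30 and MRPL50 were in LADs of both states once joined in that way. Of 76 histone genes, 0 were in naive LADs and 1, H3C6, in primed LADs. Of 44 proteasome genes, 3 were in naive and 2 in primed LADs, the difference being PSMA8, a testis-specific subunit (100% and 0%). Of 510 ZNF genes, 25 were in naive LADs and 22 in primed LADs, at percentile 0 of random lists in both. The random lists were not matched on chromosome. Shifts, which keep LADs on their chromosome, averaged 120 of the 510 ZNF genes in naive LADs, against 168 of the 379 solute carriers. ZNF genes thus lie more on chromosomes with few LADs, and percentile 0 includes this. They were also at 0 and 0 against shifts, which do not avoid genes. ZNF521 (95.8% and 0%), ZNF202 (90.7% and 0%), ZNF438 (79.9% and 0%) and ZNF189 (90.3% and 15.3%) were in naive LADs only, and ZNF827 (0% and 55.9%) in primed LADs only.

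Neuronal adhesion and receptor genes and several clustered families were often in LADs of both states. Of 26 synapse and neuron adhesion genes, 23 were in naive and 24 in primed LADs, at percentile 100 in both. Of 47 GABA and glutamate receptor genes, 24 were in naive and 25 in primed LADs. GRIN2B and GRIP1 (83.02% and 18.01%) were in naive LADs only, and GABRA3 (39.9% and 91.7%) and GABRE (46.4% and 78.3%) were among those in primed LADs only. GRIP1 was taken in by its symbol and encodes a protein that interacts with glutamate receptors, not a receptor. Of 23 cadherins, 13 and 11 were in LADs, with CDH17 (85.8% and 0%) and CDH13 (75.2% and 26.4%) in naive only. All 17 type I interferon genes, on chromosome 9, were in LADs of both states, IFNK, IFNE and IFNW1 being the longest. IFNK lies apart from the others (27524290 to 27526498) and was in naive LADs only once LADs under 50 kb were left out. Of 20 liver and plasma protein genes, 12 were in naive and 11 in primed LADs, and AFP, alpha-fetoprotein, was covered at 100% and 49.9%. Of 20 muscle genes, the same 4 were in both, the longest being RYR2, TTN and MYF5.

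Of 392 olfactory receptor genes, 186 lay in naive and 218 in primed LADs, with 13 in naive only and 45 in primed only. OR2A1, OR2A7, OR8U3 and OR6X1 were covered at 100% in naive and 0% in primed, and OR2M4, OR2T2, OR56B2 and OR9G4 at 0% and 100%. Neighbours in a cluster often share a LAD, so these genes stand for fewer loci, which were not counted for the families in this paragraph. OR2A1 and OR2A7 lie within 1 Mb on chromosome 7, and OR2M4 and OR2T2 within 1 Mb on chromosome 1. Primed stayed ahead under the 5 settings that joined or filtered the LADs, at 241 against 226 with LADs less than 50 kb apart joined. Of 94 keratin-associated protein genes, 30 and 33 were in LADs, KRTAP24-1, KRTAP25-1 and KRTAP19-6 in primed only (0% and 100%), and 33 in each state with LADs less than 50 kb apart joined. Bitter taste receptors numbered 12 and 9 of 25, with TAS2R40, TAS2R50 and TAS2R46 in naive only (100% and 0%). UDP-glucuronosyltransferases numbered 11 and 12 of 21 (UGT2B17, 41.7% and 67.2%), serpins 14 and 15 of 34 (SERPINC1, 0% and 54.2%) and beta-defensins 2 and 3 of 39 (DEFB130A, 0% and 100%). Of 379 solute carrier genes, 81 were in naive and 69 in primed LADs. This excess of 12 in naive ran from 1 (90% of the gene body) and 3 (without LADs under 100 kb) to 21 (any overlap). SLC7A14, SLC28A3, SLC2A12 and SLC2A2, a glucose transporter gene, were in naive only (100% and 0%). SLC10A5 (0% and 100%), SLC7A11, of the cystine transporter (45.9% and 97.0%), SLC9C1 (13.04% and 52.2%) and SLC71A1 (22.1% and 55.8%) were in primed only.

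**Figure D4:**
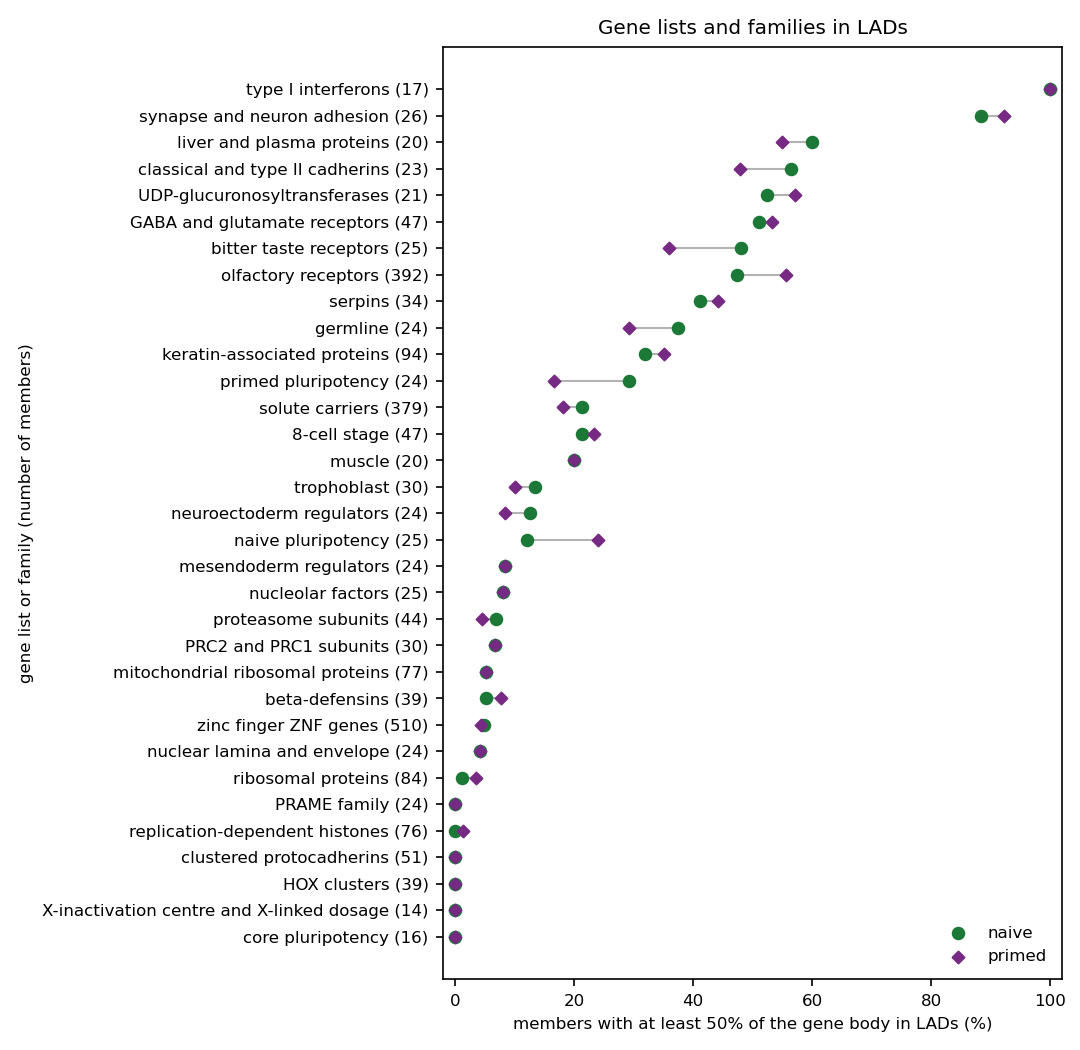
Percent of each gene list's or family's members with at least 50% of the gene body in LADs, for the naive list (circles) and the primed list (diamonds), with the number of members in brackets. Type I interferons are at 100% in both and core pluripotency genes at 0% in both.

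Several of the differences named in these lists ended under another setting. With LADs less than 50 kb apart joined, AFP, DUSP6, ENPEP, GABRA3, GABRE, MAGEA4, OR2M4, OR56B2, OR8U3, SLC10A5, SLC71A1, STC1, TAS2R40, TFAP2B and ZNF189 were in LADs of both states, besides the genes already given. Without LADs under 50 kb, CYP19A1, DEFB130A, ERVW-1, GABRE, H3C6, MRPL3, OOEP, OR2A1, OR2A7, OR6X1, OR8U3, OR9G4, SERPINC1, SLC71A1, SLC9C1, TAS2R46, TAS2R50, ZNF202 and ZNF827 were in LADs of neither. With LADs less than 100 kb apart joined, CDH13, GRIP1, MRPL3, OR2A1, OR2A7, OR2T2, OR6X1, SLC7A11, UGT2B17 and ZNF202 were also in LADs of both states. Without LADs under 100 kb, CGA, ENPEP, MAGEA4, PTPRZ1 and STC1 were also in LADs of neither.

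Percentiles against random genes and against shifts have different baselines. Of all protein-coding genes 18.9% lay in naive LADs, whereas shifted LADs do not avoid genes, so many lists stand low against shifts. For the 379 solute carriers, of which 81 lay in naive LADs, random lists averaged 72.1 and shifts 168. A low percentile against shifts thus does not set a list apart from genes in general. Random lists draw genes singly, whereas neighbours in a clustered family often share a LAD, so such families reach extreme percentiles more easily. Keratin-associated proteins stood at 99.97 and 100 among random lists but at 68.6 and 72.9 against shifts. For type I interferons the values were 100 and 100 against 93.2 and 92.6, and for clustered protocadherins 0 and 0 against 10.7 and 15.3. Above percentile 97.5 of random lists lay 11 of 33 lists in naive and 9 in primed. When the LADs were instead shifted round the chromosomes, the synapse and neuron adhesion list alone stayed above it in both states (percentiles 99.8 and 100), and the lists under percentile 2.5 went from 8 in each state to 18 in naive and 15 in primed.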

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

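The share of bases in LADs of 1 Mb or longer and the 50-point rule for genes were chosen after seeing the data. No paired analysis was possible because each state has 1 list that does not keep its replicates apart. For the same reason no replicate was left out. A stricter score threshold, transcription start sites (the gene table used here gives no strand), chromosome arms and spans without assembly gaps were planned and not run. Joining LADs under 10 kb apart, or leaving out LADs under 10 kb, changed nothing because neither list holds such gaps or LADs. Naive stayed ahead of primed in the number of LADs and in genome share under all alternatives run, and both lists overlapped 2.16 to 2.63 times the shifted mean. With LADs under 50 kb apart joined, naive held 1915 and primed 1502 LADs, of median 50 and 40 kb, with 88.3% and 91.7% of bases in LADs of 1 Mb or longer. The naive genome share was then 51.2%, the difference 5.42 points, the Jaccard index 0.839, the shared LADs 34.3% of naive and 67.3% of primed, the longest naive-only stretch 2170 kb and the excess of genes in naive LADs 544 (309 as deposited). With 100 kb, the same values were 1137 and 936 LADs, 120 and 100 kb, 92.2% and 94.1%, 52.8% (primed 47.0%), 5.86 points, 0.839, 38.8% and 69.4%, 2600 kb and 683 genes. Without LADs under 50 kb they were 3202 and 1628 LADs, 170 and 200 kb, 51.1% and 77.15%, 44.2%, 2.77 points, 70.8% and 86.1% shared, longest stretches of 1170 kb (naive only) and 1480 kb (primed only) and 176 genes. Without LADs under 100 kb they were 2202 and 1127 LADs, 310 and 450 kb, 53.8% and 79.2%, 42.1% (primed 40.4%), 1.68 points, 78.0% and 86.0% shared, 1240 and 1710 kb and 49 genes. With both (50 kb joined, then under 100 kb left out) they were 798 and 583 LADs, 640 and 930 kb, 89.97% and 93.0%, 5.14 points, 0.847, 57.4% and 89.4% shared, longest stretches of 2170 kb (naive) and 1500 kb (primed) and 497 genes. The longer median and the longer of the state-specific stretches thus changed sides between joining and filtering. On autosomes only, LADs of 1 Mb or longer held 49.3% of naive bases, and 44.9% of naive and 72.7% of primed LADs were shared. Counting 1 bp as shared gave 51.8% and 73.9%, and 80% of the length gave 41.4% and 63.8%. The excess of genes in naive LADs was 613 with any overlap and turned to -20 with 90% of the gene body. Over all annotated genes 16799 were in naive and 14865 in primed LADs, 3112 in naive only and 1178 in primed only, an excess of 1934. Naive minus primed members changed sign for 8 lists, each by few genes: to 1 for 8-cell genes and synapse genes (any overlap), to -1 for trophoblast and liver genes (LADs under 50 kb left out, or 90% of the gene body) and ZNF genes (100 kb joined), to 1 for UDP-glucuronosyltransferases (90%), to 1 or 2 for histones (joined) and to 1 or 3 for GABA and glutamate receptors (joined, or any overlap). The cause of these shifts was not tested. Of the 41 named genes in naive LADs only, 20 kept their call under all 5 settings that joined or filtered the LADs, and of the 41 in primed LADs only 13 did. With a difference of at least 50 points required, 588 genes were in naive only and 306 in primed only. SOX2 was in naive LADs only once LADs under 100 kb apart were joined. What depth limits cannot be said, since the lists carry no depth.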

Other observations

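Blocks with a wide difference in coverage were mostly higher in naive. Of 596 blocks of 5 Mb, 48 were covered over 20 points more in naive and 4 over 20 points more in primed. The blocks and genes in this paragraph were chosen after their values were seen. Block 55000001 to 60000000 of chromosome 1 was covered at 87.0% in naive and 21.6% in primed, with 7 of its 15 protein-coding genes in naive LADs only, among them DAB1, a reelin signalling gene, and PRKAA2, an AMPK subunit gene. The block at 5000001 to 10000000 of chromosome 18 was covered at 51.8% and 0.4%, with PTPRM, L3MBTL4, EPB41L3 and the laminin gene LAMA1 in naive LADs only. On chromosome 12, block 65000001 to 70000000 (62.0% and 10.8%) held GRIP1, MSRB3 and the WNT inhibitor gene WIF1. Block 130000001 to 135000000 of chromosome 11 was covered at 48.4% and 0%, with the neuronal adhesion genes OPCML and NTM in naive LADs only. In the other direction, block 95000001 to 100000000 of X was covered at 55.0% in naive and 93.0% in primed, with DIAPH2 in primed LADs only. Block 90000001 to 95000000 of chromosome 13 was covered at 61.4% and 94.2%, with GPC6 and DCT in primed LADs only.

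Of the gene classes not annotated as protein-coding, lncRNA genes leaned to naive LADs by more than protein-coding genes did, while miRNA, snoRNA and snRNA genes leaned about as little. Of 18177 lncRNA genes, 6857 lay in naive LADs (37.7%) and 5816 in primed LADs (32.0%), with 1331 in naive only and 290 in primed only. Of 443 tRNA genes, 25 and 14 were in LADs, and of 98 immunoglobulin and T cell receptor J segments, 18 and 5. Neighbouring segments may share a LAD, and their loci were not counted. The numbers were 394 and 365 of 1911 for miRNA genes, 245 and 232 of 1196 for snoRNA genes and 23 and 21 of 154 for snRNA genes. Of 46 chromosome ends of 5 Mb, 23 were covered more in naive, 5 more in primed and 18 equally, 16 of these without a LAD in either list, with a difference over 10 points at 10 ends, all higher in naive. Among these, chosen after their values were seen, the last 5 Mb of chromosome 11 were covered at 48.4% and 0%, the first 5 Mb of chromosome 10 at 59.6% and 20%, and the first 5 Mb of chromosome 5 at 32.4% and 4.2%. The first 5 Mb of chromosomes 13, 14, 15, 21 and 22 were among the 16 ends without a LAD. Assembly gaps, where no window can be called, were not taken out, so equal coverage there may have been fixed in advance.

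The tests of overall sensitivity and of chance placement below were chosen after the result was seen. The naive list had more single-window gaps between LADs, 4769 against 2584. Random loss of windows would leave gaps with the same gene content as their surroundings. Of the 2520 naive gaps that primed LADs cover, 43.4% held part of a protein-coding gene, against 34.3% of the flanked windows in LADs of both states, a ratio of 1.26 (1.16 to 1.36), which argues against random loss as the whole cause, and the primed gaps that naive LADs cover gave 1.44 (1.33 to 1.56). Windows that cannot be called in any library would be gaps in both lists, and 47.2% of the naive gaps (45.7% to 48.6%) also lay outside primed LADs, so such windows may account for up to that part and not for the rest. A lower sensitivity of the whole naive list would give less coverage in naive if lamina contact were equal in both states, which is unknown. The difference was 3.93 points the other way (3.09 to 4.87), but for that reason it cannot decide. Lower sensitivity, a flatter or noisier naive signal, a different combination of replicates and a biological difference between the states stay open, since the lists carry no signal.

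Of the few marker loci whose call differed, most lay in LADs of the state they do not mark, with VCAN going the other way. As a hypothesis, genes used in 1 state may leave the lamina there. The score, naive-only minus primed-only loci of the primed markers minus the same for the naive markers, was 4 with neighbours within 1 Mb counted once, and 2.04% of 10000 random pairs of lists scored as high. Random pairs were scored gene by gene, without joining neighbours. Scored in that way the markers reached 6, as did 0.06% of random pairs, but this counts the DPPA5 cluster more than once. With LADs less than 50 kb apart joined the locus score was 3, which 6.60% of random pairs reached, and over the 6 versions of the lists the share for the locus score ran from 1.18% to 6.60%. Chance placement cannot be told apart from a shared pattern, because few loci decide the score, and this pair of lists was picked out of 33 lists and families. No expression was measured in these files.

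Lone 10 kb windows with no other LAD within 500 kb were called 96 times in naive and 94 times in primed, and 5 of them were the same window. Mitochondrial sequence copies in the nuclear genome might draw reads to such windows, but 0 of the 5 held a mitochondrial pseudogene (0-fold the share of 0.0657% among all windows, exact binomial interval of the share 0% to 52.2%), and 5 windows are too few to decide. Among them, chosen after it was seen, that on chromosome 19 (55650001 to 55660000) overlaps CCDC106 and U2AF2, which encodes a splicing factor.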
